A study of Saccharomyces cerevisiae with 19 samples.

How the data were processed

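The series holds 19 samples of budding yeast (Saccharomyces cerevisiae, BY4741 background). Transcript levels were measured by RNA-seq in 6 libraries, 2 each from young cells, from old cells and from old cells of a strain built to over-express histones H3 and H4. The 9 MNase-seq libraries and the 4 genome sequencing libraries are not analysed here. Per the labels' protocols, old mother cells were obtained with the mother enrichment programme, in which estradiol switches on a recombinase that stops daughter cells from dividing further. Biotin-marked mothers were aged for 36 h and recovered on streptavidin beads. Young cells were biotin-marked, grown overnight and recovered on the same kind of beads. The wild-type strain (ZHY2) gave the young and old cells, and the over-expression strain (JFY087) was grown with 2% raffinose and 0.5% galactose, which induces the GAL1/10 promoter that drives its extra H3 and H4 genes. The labels describe glucose medium for general growth and raffinose with galactose for the ageing culture, and do not state plainly which of them the wild-type cells of the young and old libraries had. RNA was treated with DNase I, depleted of ribosomal RNA and mixed with the ERCC set of 92 synthetic transcripts in an amount set by cell number, per the labels' protocols. Libraries were made with a strand-marking kit (ScriptSeq v2), and whether strand was used in counting is not given in the sources used here.

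The authors deposited a single expression table with a value for each of 6147 features in each library, of which 6099 are genes and 48 are ERCC transcripts. The deposited values are RPKM (reads per kilobase and per 1e6 reads) multiplied by 1 factor per library. This was read from the values, which in each library are whole multiples of 0.01 times that factor. The factors were 7.53 and 5.24 for young replicates 1 and 2, 10.92 and 16.54 for old, and 8.75 and 13.76 for old with H3/H4 over-expression. They put the ERCC transcripts at nearly 1 level. The median difference of the 24 abundant ERCC transcripts from their means over libraries ran from -0.15 to 0.13 between libraries on the log2 scale. Per the submitters' processing notes, TopHat, Bowtie and Cufflinks were used with build sacCer3. Versions, the annotation and the way the factor was computed are not given in the sources used here. Because the factor rests on RNA added per cell, a shift of all genes between libraries enters the deposited values and would be removed by any scaling to a library median. Both scales were therefore analysed.

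Sequencing depth was recovered from the low values. A gene with few reads takes values in steps of 1 read, whose size depends on gene length and depth, and the step sizes gave 28.6 and 27.9 (in 1e6 reads) for young replicates 1 and 2, 24.1 and 22.2 for old, and 25.6 and 24.7 for the over-expression libraries. With these depths 92.1% to 93.9% of the low values came out as whole reads within 0.2 reads, against 42.2% in simulated values without steps, and 3 of 3 simulated depths were recovered. The median gene had 1206 to 1849 reads per library, so counting error was small for most genes, and the number of libraries set the precision. Reads without molecular identifiers are not independent molecules. The values remained RPKM in every test, since the read counts were used only to describe depth.

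Genes were matched by systematic name to the NCBI RefSeq annotation of assembly R64, the same reference sequence as sacCer3. Of the 6099 genes, 5727 matched and 372 did not. Coordinates are 1-based from that annotation. There are 37 genes whose values equal those of another gene in all 6 libraries, and these, like members of near-identical families and genes antisense to another transcript, are reported as uncertain. No column of values from other samples was present (0 columns).

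Tests were fixed before the data were examined. Values were transformed as log2(value + 1), so that a change in a gene with low values is understated, and the 3 groups were fitted together in limma (lmFit and eBayes with a mean-variance trend) without a replicate term. One fit used the deposited values and the other the same values after the library median had been subtracted, called relative to the library median below. P-values were adjusted by the Benjamini-Hochberg method over the 6099 genes, and 0.05 was the threshold. The filter, a mean of at least 1 over the 6 libraries, removed 0 genes. Simulated data with the residual spread of these libraries, relative to the library median, were tested first. With 200 changed genes among 6099 in the comparison of old with young, 14.4% of changes of 1 on the log2 scale, 79.9% of changes of 2 and 92.9% of changes of 3 were called, with a mean of 8.3 unchanged genes called. The unit was assumed to be FPKM when the tests were fixed, and RPKM needed no other test.

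Before the data were examined 33 gene lists were fixed, of which 32 were tested as sets with camera (inter-gene correlation 0.01, median-centred values) and the last, of genes engineered in the strains and of mating loci, was read gene by gene. In 10 of 10 simulations a list shifted by 1 was found, and 0 unshifted lists were called. The simulated genes were drawn independently of each other, so this does not check the test where list members vary together. Counts of list members past the threshold are given over all genes and, where said, adjusted over the list alone. A shift of the library medians was tested by a two-sided exact permutation test of 2 against 2 libraries, which cannot give p below 0.333. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

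Genes were named by a rule fixed before the data were examined. For old against young, and for over-expression against old, the rule takes the 8 largest increases and 8 largest decreases relative to the library median among genes with adjusted p under 0.05, a mean of at least 10 in the higher group, no overlap between the libraries of the 2 groups and a standard symbol. It takes 4 in each direction for over-expression against young. Where fewer genes pass, all that pass are named. The rule also takes all measured core histone, galactose regulon and strain design genes whatever their values, and the 2 to 4 members with the smallest p in each list described. Any other gene is said to have been chosen after its values were seen.

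The alternatives were pseudocounts of 0.1 and 5, a filter at a mean of 5 or none, eBayes without the trend, the replicate number as a block, the 2 compared groups alone, quantile and upper-quartile scaling, scaling by the ERCC transcripts, each library left out in turn, camera with an estimated correlation, and fry. RPKM before the library factor, quantile scaling with the block, list tests under quantile scaling or with both an estimated correlation and the block, shifts within 1 replicate number and a split of the young libraries were added after the data were seen. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.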

Results

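Transcript levels were measured by RNA-seq in young yeast cells, in replicatively old mother cells, and in old mother cells of a strain carrying galactose-inducible histone H3 and H4 genes, with 2 libraries per group. Depth, recovered from the smallest steps of the deposited values, lay between 22.2 and 28.6 (in 1e6 reads) per library. The values are RPKM multiplied by a factor per library that levels RNA spiked in by cell number, so that the deposited scale compares amounts per cell as far as the spike-in holds. Levels below are deposited values as mean ± SD over the 2 libraries of a group. Log2 changes are limma estimates relative to the library median unless the deposited scale is named, with the standard error (SE) after the sign ±.

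The first comparison, old against young, asks how the transcriptome of a mother cell changes with replicative age. Old cells came from the mother enrichment programme and 36 h of culture, and young cells from overnight growth. Effects of the programme and of culture time therefore cannot be told apart from those of age. This holds for each comparison with young, and a change with age below means a difference between old and young libraries. Relative to the library median, lists of meiosis and sporulation, mating, cell wall and cell cycle genes passed the camera test toward higher levels in old cells. Lists of the cytosolic and mitochondrial ribosome, ribosome assembly, the daughter-specific programme and galactose use passed toward lower levels (the mitochondrial ribosome list only on this scale). With a correlation estimated from the libraries 0 of 32 lists passed (smallest camera adjusted p = 0.290). In most lists only a part of the members was called. Camera did not match lists to genes of a like level. Low genes rose more than high genes, and the list calls are not parted from that trend. SPO74, which acts late in sporulation, went from 2.19 ± 0.973 to 148 ± 48.3 (n = 2 per group), and the G1 cyclin gene CLN2 from 62.6 ± 20.3 to 647 ± 102. The ribosomal protein gene RPL22A went the other way, from 9897 ± 4498 to 3951 ± 2683. On the deposited scale most genes stood higher in old cells, with a median log2 change of 0.91. There the ribosomal protein genes had a median of -0.70 with 0 of 135 called, and -1.89 and 0.43, the opposite sign, within replicate numbers 1 and 2.

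Of 6099 genes, 1351 passed adjusted p 0.05 in limma relative to the library median, 806 of them higher and 545 lower in old cells (2476 at unadjusted p under 0.05). As deposited, 614 passed, 610 higher and 4 lower (1472 unadjusted). Upper-quartile scaling gave 1300 higher and 259 lower, scaling by the ERCC transcripts 458 higher and 2 lower, and on RPKM before the library factor without centring 458 were higher and 281 lower. Without old replicate 1 or without old replicate 2 the count relative to the library median was 0, in limma with the lone library assumed to vary like the other groups (1263 and 1833 unadjusted). Every call relative to the median in this comparison, those of named genes included, thus needs both old libraries. Without over-expression replicate 1 or 2, which add only to the estimate of spread, it was 261 or 275. The calls lost in 1 or both of these cases, at adjusted p from 0.0502 for GAL2 to 0.116 for HHF2, included those of ERR3, TAR1, PAU4, RPL9A, RPS9B and RPL19B, of all 5 core histone genes, of all 5 galactose genes and of CDC20, ADH1, PGK1, RNR3, PRM1, GSY1 and ERG2 among the genes named below. After quantile scaling PAU4, CDC20, RNR3, RAD53 and PRM1 also lost theirs (adjusted p = 0.0603, 0.0530, 0.0587, 0.104 and 0.144). As deposited the count was 377 without young replicate 1, 129 without young replicate 2, 231 without old replicate 1 and 79 without old replicate 2.

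Among the 646 genes that met the conditions for an increase, DPA10 (YLR307C-A, chromosome XII, 746848 to 747111, build sacCer3) had the largest estimate with the pseudocount of 1. It rose from 53.3 ± 16.1 to 7569 ± 4477, a log2 change of 6.09 ± 0.41 (limma adjusted p = 0.00444). PHO92 (YDR374C, chromosome IV, 1223474 to 1224394), which encodes a reader of methylated adenosine in RNA, rose from 2.75 ± 2.71 to 252 ± 105, or 5.30 ± 0.71 (adjusted p = 0.0132). DAL80 (YKR034W, chromosome XI, 506898 to 507707), a repressor of nitrogen catabolism genes, rose from 4.72 ± 1.56 to 321 ± 73.8, or 4.90 ± 0.45 (adjusted p = 0.00878). The other 5 share sequence with other genes and are uncertain. TAR1 (YLR154W-C, chromosome XII, 454696 to 455070), which lies antisense to the 25S rRNA gene in the repeated rDNA, went from 9795 ± 697 to 671863 ± 211833 (log2 5.14 ± 1.06, adjusted p = 0.0267), and its call was lost without young replicate 1 or 2 (adjusted p = 0.102 and 0.0838). Whether strand was used in counting is not given. Reads of 25S rRNA left after depletion therefore cannot be told apart from those of TAR1. ERR3 (YMR323W), an enolase-like gene with near-identical copies, changed by 5.27 ± 0.99 and its neighbour SNO4 (YMR322C), of the HSP31 family, by 4.98 ± 0.43. DDI3 (YFL061W), nearly identical to DDI2, was listed at 0 in both young libraries and at 127 and 94.9 in old. Its estimate of 5.86 therefore depends on the pseudocount, and so does its rank below DPA10. PAU4 (YLR461W), of the seripauperin family, was listed at 0 in both young libraries and at 24.0 and 109 in old replicates 1 and 2.

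There were 525 genes that met the conditions for a decrease. AAH1 (YNL141W, chromosome XIV, 359596 to 360639), which encodes adenine deaminase, fell from 1345 ± 1054 to 202 ± 164, a log2 change of -3.67 ± 0.50 (limma adjusted p = 0.0137). FIT2 (YOR382W, chromosome XV, 1059531 to 1059992), a cell wall mannoprotein of siderophore-iron uptake, fell from 2320 ± 1416 to 463 ± 241 (-3.20 ± 0.40, adjusted p = 0.0125). UBC9 (YDL064W, chromosome IV, 337487 to 338070), the SUMO-conjugating enzyme and a target of the recombinase in the mother enrichment programme, fell from 471 ± 87.5 to 102 ± 51.4 (-3.20 ± 0.24, adjusted p = 0.00444). The daughter-specific genes DSE1 (YER124C) and DSE3 (YOR264W) fell by 2.79 and 2.44 on the log2 scale. RPL9A, RPS9B and RPL19B, ribosomal protein genes with near-identical copies elsewhere, changed by -2.47, -2.45 and -2.44. All 8 stood below 0 on the deposited scale too, where AAH1, FIT2 and UBC9 passed (adjusted p = 0.00959, 0.0474 and 0.0451) and the other 5 did not. The only other decrease as deposited, HOR7, was chosen after its values were seen. It was listed at 0 in old replicate 1 and at 141 in old replicate 2, which overlaps the young libraries at 38.0 and 284.

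Of the 32 lists tested, 17 passed camera in old against young, 6 toward higher and 11 toward lower levels. With a correlation estimated from the libraries 0 of them passed, the smallest camera adjusted p being 0.290. The fry test, which asks whether a list moves on balance in 1 direction, passed 12 of the 32. They included histone regulation (fry adjusted p = 0.0435), which did not pass camera. Ribosome biogenesis, ergosterol, proteasome, glycolysis, respiratory and Msn2/4 lists passed camera but not fry (fry adjusted p = 0.168, 0.0749, 0.0502, 0.480, 0.454 and 0.456). The 30 of 54 genes of meiosis and sporulation that rose included MND1, which acts in recombination, at 3.26 ± 0.33, SPO77 at 4.42 ± 0.47 and SPO74 at 4.61 ± 0.50, while 0 fell (list median 1.73, camera adjusted p = 1.32e-09, adjusted p = 0.290 with an estimated correlation). Adjusted over the list alone 32 rose. In the mating and pheromone list 14 of 27 genes rose and 0 fell, with a median of 1.67 (camera adjusted p = 0.000344, adjusted p = 0.488 with an estimated correlation), and 16 rose and 2 fell adjusted over the list alone. The agglutinin genes AGA2 and SAG1 rose by 4.22 ± 0.63 and 2.22 ± 0.31, and the membrane fusion gene PRM1 by 1.81 ± 0.31. Cell wall genes rose in 15 of 35 cases and fell in 0 (median 1.37, camera adjusted p = 3.62e-06, adjusted p = 0.488 with an estimated correlation, 17 adjusted over the list alone), among them PIR3 from 56.7 ± 20.8 to 2328 ± 1606 and the protease gene YPS3 from 23.6 ± 1.93 to 526 ± 205.

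Cell cycle genes also rose. The G1/S list had 19 of 32 members higher and 0 lower, with a median of 1.10 (camera adjusted p = 2.82e-07, adjusted p = 0.419 with an estimated correlation), and 23 higher adjusted over the list alone. CLN2 rose by 2.45 ± 0.27, the forkhead factor gene HCM1 by 2.09 ± 0.21 and SWI4, which drives G1 transcription, by 1.70 ± 0.20. In the G2/M and M/G1 list 12 of 30 rose and 1 fell (median 0.99, camera adjusted p = 2.71e-05, adjusted p = 0.551 with an estimated correlation), with 16 higher and 2 lower adjusted over the list alone. Its member BUD4, needed for bud site selection, rose from 85.4 ± 29.8 to 723 ± 192. DNA damage response genes had 8 of 26 higher and 1 lower (median 0.64, camera adjusted p = 0.00153, adjusted p = 0.290 with an estimated correlation), with 11 higher and 3 lower adjusted over the list alone. The recombination gene RAD54 rose from 98.9 ± 27.9 to 686 ± 310, the ribonucleotide reductase gene RNR3 from 26.3 ± 2.37 to 265 ± 19.4, and the checkpoint kinase gene RAD53 changed by 1.88 ± 0.35.

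Ribosome genes made up the largest lists to fall. Of 135 cytosolic ribosomal protein genes 93 fell and 0 rose, with a median of -1.63 (camera adjusted p = 2.77e-26, adjusted p = 0.488 with an estimated correlation), and 115 fell adjusted over the list alone. Many have near-identical copies. RPL22A changed by -2.36 ± 0.31 and RPS4B by -1.92 ± 0.24. Among ribosome biogenesis genes 23 of 80 fell and 0 rose (median -1.05, but -0.12 with 0 called as deposited, camera adjusted p = 1.43e-11, adjusted p = 0.671 with an estimated correlation, 26 adjusted over the list alone), with RLP7 at -2.24 ± 0.28 and the RNA helicase gene DBP2 at -2.17 ± 0.31. Mitochondrial ribosomal protein genes fell in 27 of 70 cases, with a median of -0.85 relative to the library median and 0.07, the opposite sign, as deposited (camera adjusted p = 1.43e-11, adjusted p = 0.290 with an estimated correlation, 41 adjusted over the list alone). MRPL31 changed by -1.51 ± 0.19. Of 13 daughter-specific genes 8 fell and 0 rose (median -1.60, and -0.67 with 0 called as deposited, camera adjusted p = 2.95e-06, adjusted p = 0.290 with an estimated correlation, 10 adjusted over the list alone), DSE4 and SUN4 by -2.18 ± 0.21 and -1.80 ± 0.20.

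The glycolysis and fermentation list had a median of -1.08, and -0.15 with 0 lower calls as deposited, with 4 of 18 genes lower and 2 higher (camera adjusted p = 0.0124, adjusted p = 0.844 with an estimated correlation), and 6 lower and 2 higher adjusted over the list alone. Phosphoglycerate kinase PGK1 changed by -1.80 ± 0.41 and alcohol dehydrogenase ADH1 by -2.21 ± 0.54, against 4.49 ± 0.32 for the minor pyruvate decarboxylase PDC6. Ergosterol genes fell in 6 of 23 cases, also adjusted over the list alone, with a median of -0.69 that was 0.23 as deposited (camera adjusted p = 0.000413, adjusted p = 0.566 with an estimated correlation), and ERG2 changed by -1.52 ± 0.29. The nuclear respiratory chain list, with 1 of 35 genes lower (CYC7, -1.14 ± 0.28), had a median of -0.53 and of 0.39 as deposited (camera adjusted p = 0.0180, adjusted p = 0.844 with an estimated correlation, 0 adjusted over the list alone). The Msn2/4 stress, trehalose and glycogen list had 5 of 32 genes lower, also adjusted over the list alone, and 1 higher, with a median of -0.46 that was 0.47 as deposited (camera adjusted p = 0.0444, adjusted p = 0.844 with an estimated correlation). Glycogen synthase GSY1 changed by -1.62 ± 0.27 and the higher member, GND2 of the pentose phosphate pathway, by 1.93 ± 0.25. Proteasome genes had 3 of 33 lower (RPT6 -0.92 ± 0.23, PUP2 -0.88 ± 0.22, RPN11 -0.78 ± 0.19) and a median of -0.52, and the list and these 3 genes turned positive as deposited, at 0.41, 0.00, 0.05 and 0.14 (camera adjusted p = 0.000225, adjusted p = 0.566 with an estimated correlation, 0 adjusted over the list alone). Without young replicate 2 the glycolysis, respiratory and Msn2/4 lists lost their calls (camera adjusted p = 0.0918, 0.660 and 0.768), and without old replicate 1 the latter 2 did (0.0716 and 0.225). After quantile scaling the glycolysis, ergosterol, respiratory, Msn2/4 and proteasome lists lost theirs (0.370, 0.0720, 0.663, 0.861 and 0.663), the proteasome median turning to 0.02. So did ADH1, PGK1, ERG2, CYC7, RPT6, PUP2 and RPN11 in limma (adjusted p from 0.0598 to 0.390). Of the genes named here, ADH1, CYC7, PUP2 and RPN11 lost their calls in limma without young replicate 1 (adjusted p = 0.0665, 0.0594, 0.0503 and 0.0528) and without young replicate 2 (0.0862, 0.0699, 0.0673 and 0.0586). PGK1 and RPT6 lost theirs without young replicate 2 (0.0679 and 0.0720).

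The core histone and galactose genes were read whatever their values, because the strain of the third group carries H3 and H4 genes on a galactose promoter. Of 8 core histone genes 5 fell and 0 rose relative to the library median (list median -1.20, camera adjusted p = 0.000998, adjusted p = 0.518 with an estimated correlation), and 6 fell adjusted over the list alone. HTA1 changed by -1.61 ± 0.37, HTA2 by -1.57 ± 0.33, HTB1 by -1.33 ± 0.24, HHT1 by -1.16 ± 0.30 and HHF2 by -0.98 ± 0.25, with limma adjusted p between 0.0204 and 0.0439. Without young replicate 1 the calls of HTA2, HHT1 and HHF2 were lost (adjusted p = 0.0579, 0.0740 and 0.0715), and without young replicate 2 those of HHT1, HHF2, GAL3 and GCY1 (0.0764, 0.0686, 0.0610 and 0.0860). After quantile scaling all 5 histone calls were lost, at adjusted p from 0.0754 (HTB1) to 0.367 (HHF2). HTB2, HHF1 and HHT2 did not pass, at -1.23, -0.87 and -0.90. As deposited the list median was -0.27, 0 histone genes passed, and HHF1 and HHT2 stood at 0.05 and 0.02. GAL1 was abundant in young cells, at 41356 ± 3960 against 20466 ± 11755 in old. It changed by -2.07 ± 0.39 and the galactose permease gene GAL2 by -2.13 ± 0.31, and GAL7 and GCY1 also fell (-1.73 and -1.65). GAL3 fell by 0.78 relative to the library median but stood at 0.15 as deposited. GAL10 and the repressor gene GAL80 did not pass, at -1.22 and 0.69. The galactose list thus had 5 of 7 lower and 0 higher (median -1.65, and -0.73 with 0 called as deposited, camera adjusted p = 0.00686, adjusted p = 0.488 with an estimated correlation), and 6 lower and 1 higher adjusted over the list alone. It lost its call after quantile scaling (adjusted p = 0.0630), as did GAL1, GAL3, GAL7 and GCY1 (limma adjusted p = 0.0625, 0.142, 0.0622 and 0.105). The labels do not state plainly in which sugar the young and old wild-type cells grew. GAL7 had means of 11471 in young, 6989 in old and 5740 in the over-expression strain grown with galactose, against library medians of 221 to 711. GAL1 was high in young and old as well. These levels argue against growth in glucose without galactose in either wild-type group. Another difference in medium is not excluded as the source of these changes. Of the other strain design genes, the recombinase target CDC20 rose by 1.00 ± 0.26 (limma adjusted p = 0.0456), a call lost without young replicate 2 (adjusted p = 0.0964), while LYS2 stood at 0.48, HIS3 at 0.59 and ADE2 at 0.41 without passing. URA3 at -0.81, HO at -0.72 and LEU2 at -0.03 did not pass either, and turned to 0.12, 0.21 and 0.90 as deposited. MATALPHA2 stood at -0.69 and MATALPHA1 at -0.89 (0.24 and 0.04 as deposited, the opposite sign) and HMRA2 at 0.22 without passing, and the MAT and HML alpha genes had equal values.

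The 15 lists that did not pass in old against young had camera adjusted p from 0.0709 for silencing factors (median 0.54) to 0.791 for amino acid biosynthesis (-0.10). The others were histone regulation (0.61), histone variants (-0.20), hexose transport (-0.48), gluconeogenesis (1.03), the tricarboxylic acid cycle (-0.24), mitochondrially encoded genes (0.37), RNA polymerases I and III (-0.42), heat shock (0.21), oxidative stress (-0.48), autophagy (0.08), the iron and phosphate regulons (-0.51 and -0.14) and chromatin remodellers (0.01), and every median below 0 in this paragraph turned positive as deposited, from 0.42 for the iron regulon to 0.82 for amino acid biosynthesis.

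**Figure D1:**
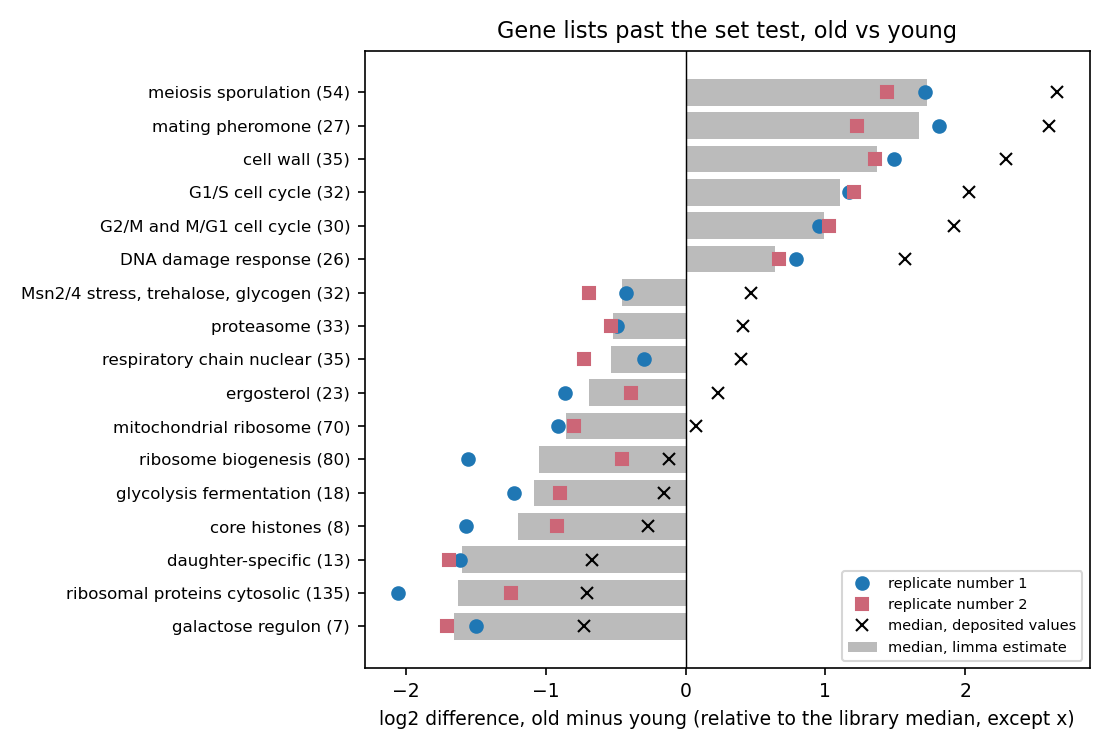
Horizontal bars give the median log2 difference, old minus young, of each gene list past the camera test, relative to the library median, with the number of measured genes in brackets, circles and squares the same within replicate numbers 1 and 2, and crosses the median on the deposited values. Bars run from -1.65 (galactose regulon) to 1.73 (meiosis and sporulation), and the crosses of the mitochondrial ribosome, ergosterol, respiratory chain, Msn2/4 stress and proteasome lists lie on the other side of 0.

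On the deposited scale 87.2% of genes stood higher in old than in young cells, with a median change of 1.87-fold. The library medians on the log2 scale were 8.37 and 7.79 in young replicates 1 and 2, and 8.54 and 9.48 in old, so that the group means were 8.08 ± 0.41 and 9.01 ± 0.66 (SD, n = 2). A difference of this size had p = 0.333 in the exact permutation test, the smallest p that 2 against 2 libraries allow. Within replicate number 1 the median gene was 1.10-fold higher in old cells and 55.8% of genes were higher, and within number 2 it was 3.17-fold higher with 98.8% of genes higher. On RPKM before the library factor the median shift was -0.18. Each value within a replicate number rests on 1 library per group, and the labels give no pairing. These values show that the shift varied widely between libraries, not that it depends on the replicate number.

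**Figure D2:**
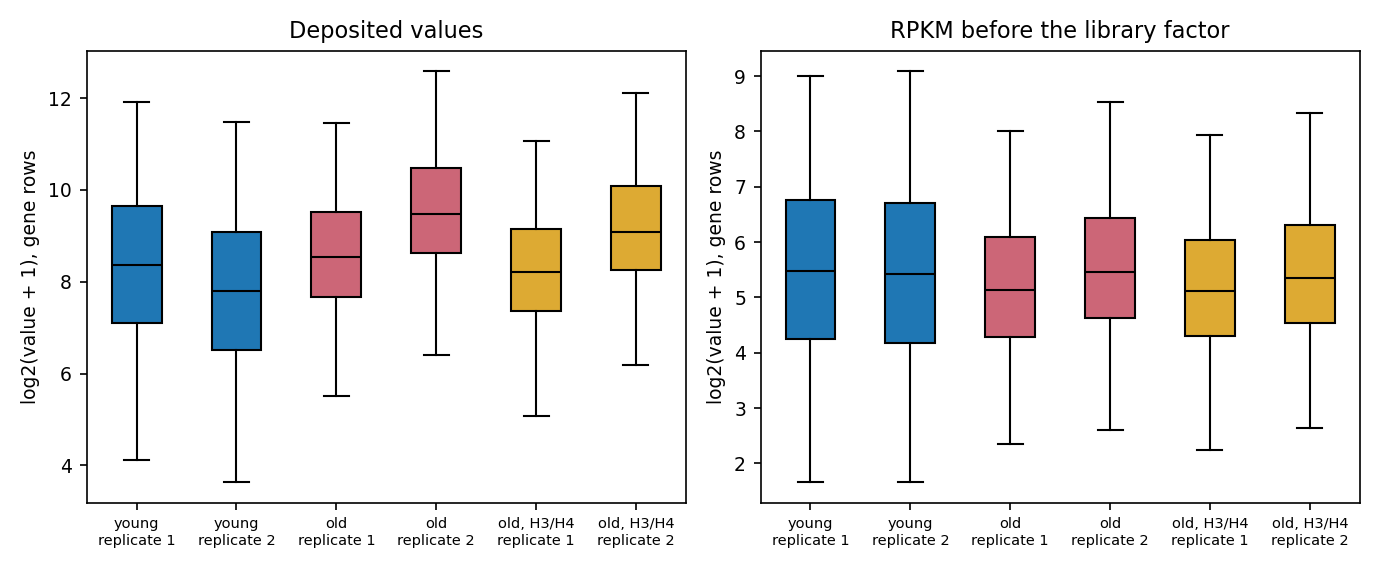
Boxes show the log2(value + 1) of 6099 genes in each of the 6 libraries, on the deposited values (left) and on RPKM before the library factor (right), with the median, the quartiles and whiskers from the 5th to the 95th percentile. Deposited medians run from 7.79 (young replicate 2) to 9.48 (old replicate 2), and the boxes of the 4 libraries from old cells are narrower than those of the young libraries on both scales.

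Low genes rose more than high genes in old cells. With genes in 5 equal groups by mean level, the median log2 change as deposited was 1.63 in the lowest group, 1.17, 0.89 and 0.65 in the next 3 and 0.41 in the highest. Within replicate number 1 it ran from 0.93 to -0.35, and within number 2 from 2.34 to 1.16. This trend may enter the list calls, since camera did not match lists by level. As deposited the DNA damage (1.57), Msn2/4 (0.47) and proteasome (0.41) list medians lay within the range of the group medians. The other called lists lay outside it, up to 2.65 for meiosis and sporulation and down to -0.73 for galactose. The levels of list members were not compared. The interquartile range between genes was 2.56 and 2.58 in the young libraries and 1.85 and 1.86 in the old libraries, a difference of means of -0.72 (exact permutation p = 0.333, the smallest possible).

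**Figure D3:**
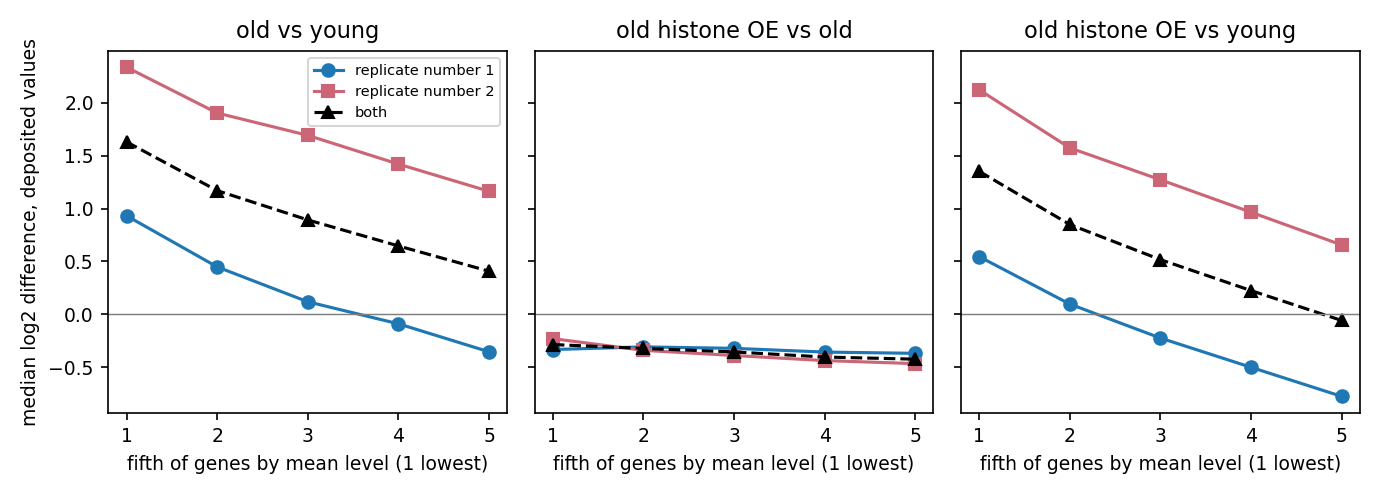
The median log2 difference of the deposited values (y axis) is plotted for 5 groups of genes by mean level (x axis, 1 lowest, 1219 or 1220 genes each) in the 3 comparisons, with circles for replicate number 1, squares for number 2 and triangles for the limma estimate from both. In old vs young the line falls from 1.63 to 0.41 and lies lower in number 1 than in number 2, while in over-expression vs old it stays between -0.29 and -0.42.

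By chromosome, genes of chromosome XII, which carries the rDNA array, had a median change of 0.25 relative to the library median (524 genes), and those of chromosome IX 0.21 (220 genes). The other nuclear chromosomes lay between -0.17 (II) and 0.07 (I). Genes within 20 kb of a chromosome end stood at a median of 0.97 (203 genes) against -0.08 for the other 5505 genes, 76 of them rising and 3 falling (camera p = 8.78e-11, p = 0.0926 with an estimated correlation). The medians were 1.22 and 0.73 within replicate numbers 1 and 2, and 13 of the 203 share their values with another gene, so that reads of repeated chromosome ends are not assigned to a single gene there.

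The second comparison sets old cells of the H3/H4 over-expression strain against old wild-type cells, and asks what extra H3 and H4 change in old cells. The groups are different strains, and the medium of the wild-type cells is not stated plainly. Effects of strain, and possibly of medium, therefore cannot be told apart from those of extra H3 and H4. None of the H3 and H4 genes, which check the labels, was called higher in the libraries labelled histone over-expression. HHT1 stood at 3073 ± 1665 against 4849 ± 3352 in old, a log2 difference of -0.22 (95% interval -0.95 to 0.52), HHT2 at 8190 ± 4936 against 9402 ± 7401 (0.28, -0.68 to 1.25), HHF1 at 1595 ± 788 against 2420 ± 1290 (-0.22, -0.90 to 0.45) and HHF2 at 4445 ± 1878 against 4770 ± 2861 (0.33, -0.29 to 0.96). The 4 differences were all below 0 as deposited, HHT2 and HHF2 turning to -0.08 and -0.03. The intervals include 0 and do not exclude a rise of HHT2 or HHF2. GAL1 was nearly level at 15235 ± 7337 and 20466 ± 11755 (log2 -0.02, interval -0.99 to 0.94). The libraries are therefore called by their label, since the transcripts of the over-expressed genes do not set them apart.

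In limma 0 of 6099 genes passed adjusted p 0.05 in the libraries labelled histone over-expression against old, as deposited and relative to the library median (8 at unadjusted p under 0.05 in each). URA3 (YEL021W, chromosome V, 116167 to 116970), a uracil synthesis gene used as a strain marker, had the smallest p. It stood at 827 and 1272 in old replicates 1 and 2 and at 5390 and 8738 in the libraries labelled over-expression, 6.52-fold and 6.87-fold higher within each replicate number. The log2 difference was 3.10 ± 0.26 (interval 2.46 to 3.74, limma adjusted p = 0.166), which failed the correction in the fit without a replicate term. It passed only with the replicate number as a block (limma adjusted p = 0.0208), a pairing that the labels do not give. The lowest library labelled over-expression was 4.24-fold above the highest old library. The remaining histone, galactose and strain design genes lay between -0.60 (HMRA2) and 0.33 (HHF2), with limma adjusted p of 1, and those above 0 turned below 0 as deposited. Without old replicate 2 the deposited values gave 2 calls, YOL103W-A (a transposon gene with many copies) and HOR7, chosen after their values were seen.

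**Figure D4:**
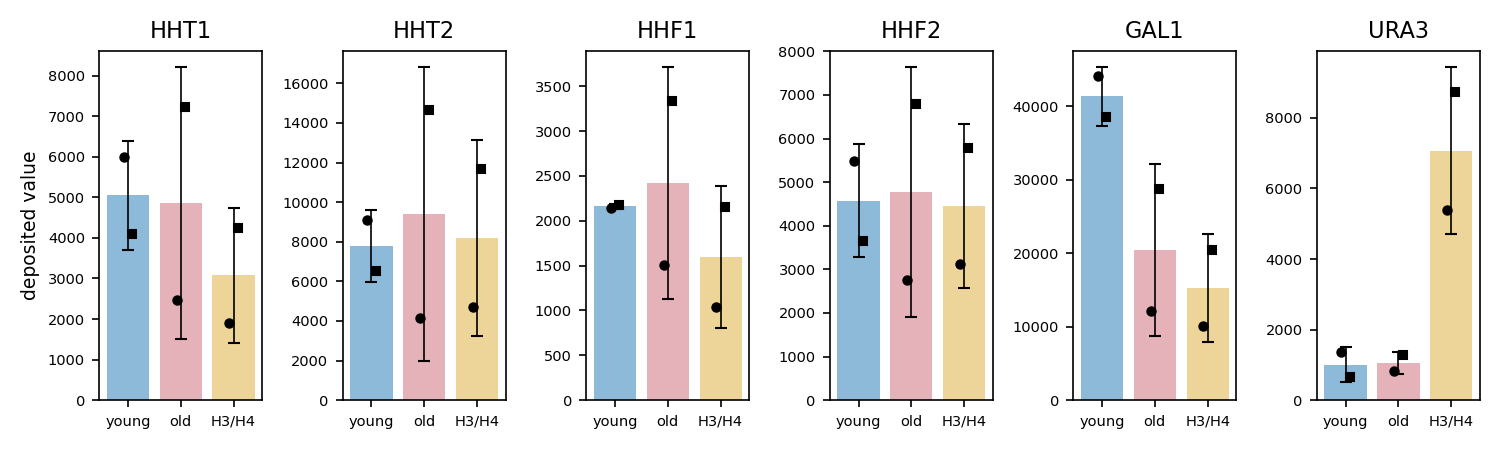
Bars give the mean deposited value of the H3 genes HHT1 and HHT2, the H4 genes HHF1 and HHF2, GAL1 and URA3 in young cells, old cells and the old libraries labelled H3/H4 over-expression, with error bars of 1 SD (n = 2), circles for replicate 1 and squares for replicate 2, each panel on its own linear axis from 0. Of the 6 genes URA3 alone has both libraries labelled over-expression (5390 and 8738) above both old libraries (827 and 1272).

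Of the 32 lists 5 passed camera in this comparison, with small medians and with 0 members called, also adjusted over the list alone. They were mitochondrial ribosomal proteins at -0.12, the Msn2/4 stress list at -0.19, the proteasome at -0.10, mating genes at 0.15 and cell wall genes at 0.13 (camera adjusted p = 3.73e-05, 0.000637, 0.00230, 0.0311 and 0.00230). Each had adjusted p = 0.998 with an estimated correlation, and 0 passed in fry. The mating and cell wall medians were -0.21 and -0.23 as deposited, and the Msn2/4 median turned to 0.07 without old replicate 2 and to 0.01 without over-expression replicate 1. Leaving out old replicate 1, over-expression replicate 1 or over-expression replicate 2 gave 12, 8 or 12 lists. The mating list lost its call without old replicate 2, over-expression replicate 1 or over-expression replicate 2 (camera adjusted p = 0.578, 0.137 and 0.143), the cell wall list without old replicate 1 or over-expression replicate 2 (0.117 and 0.578), the proteasome list without old replicate 2 or over-expression replicate 1 (0.411 and 0.422), and the mitochondrial ribosome list without old replicate 2 (0.293). After quantile scaling the proteasome and mating lists lost theirs (0.239 and 0.0902). Examples such as MRP7 (-0.26 ± 0.18), GSY2 (-0.29 ± 0.24), RPN11 (-0.21 ± 0.19), FAR1 (0.24 ± 0.20) and RLM1 (0.35 ± 0.23) lay within 2 SE of 0, and FAR1 and RLM1 turned to -0.12 and -0.01 as deposited. The core histone list did not pass (median -0.03, camera adjusted p = 0.967), nor did the galactose list, at 0.11 and -0.25 as deposited.

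On the deposited scale 3.74% of genes stood higher in the libraries labelled over-expression than in old, with a median shift of -0.36, or 0.777-fold. The shift was -0.34 and -0.38 within replicate numbers 1 and 2, yet the library medians of 8.21 and 9.09 against 8.54 and 9.48 overlapped (8.65 ± 0.63 against 9.01 ± 0.66, n = 2, exact permutation p = 0.667). On RPKM before the library factor it was -0.07. The shift was -0.29 in the lowest of the 5 groups by level and -0.42 in the highest, and the interquartile range was 1.79 and 1.81 against 1.85 and 1.86. Chromosome XII stood at -0.01 and the genes near chromosome ends at 0.06 relative to the library median (camera p = 0.000102, p = 0.241 with an estimated correlation).

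The third comparison sets the libraries labelled histone over-expression against young cells. DPA10 and PHO92, named above for their rise with age, stood high here as well. DPA10 was at 7946 ± 3819 against 53.3 ± 16.1 in young (log2 6.57 ± 0.41, limma adjusted p = 0.00330) and PHO92 at 226 ± 94.8 against 2.75 ± 2.71 (5.51 ± 0.71, adjusted p = 0.0103). ERR3 and TAR1, both uncertain for their repeats, stood 5.52 and 5.18 higher, and TAR1 lost its call without young replicate 1 or 2 (adjusted p = 0.0940 and 0.0763). FIT2, UBC9, AAH1 and DSE1 changed by -3.53, -3.49, -3.48 and -3.19. Relative to the library median 1708 genes passed in limma, 977 higher and 731 lower (2667 unadjusted), and 371 higher and 4 lower as deposited (1079 unadjusted). The 4, also below 0 relative to the median, were FIT2, UBC9, AAH1 and DSE1. Upper-quartile scaling gave 1489 higher and 336 lower, ERCC scaling 285 and 3, and RPKM before the factor without centring 575 and 633. Without over-expression replicate 1 or 2 the count relative to the median was 0 (1557 and 1845 unadjusted), and without old replicate 1 or 2 it was 828 or 836. As deposited it was 224 and 94 without young replicates 1 and 2, and 215 and 53 without over-expression replicates 1 and 2.

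Of the 32 lists 17 passed camera here, 6 higher and 11 lower, and 0 with an estimated correlation. These lists, too, were not matched to genes of a like level. Meiosis and sporulation genes rose in 30 of 54 cases (median 1.77, camera adjusted p = 4.42e-09, adjusted p = 0.365 with an estimated correlation, 35 higher and 1 lower adjusted over the list alone), SPO74 by 4.60 ± 0.50. Cytosolic ribosomal protein genes fell in 93 of 135 (median -1.66, camera adjusted p = 5.35e-24, adjusted p = 0.541 with an estimated correlation, 115 adjusted over the list alone), RPL22A by -2.57 ± 0.31. The G1/S list had 21 of 32 higher, also adjusted over the list alone (median 1.22, camera adjusted p = 4.05e-07, adjusted p = 0.431 with an estimated correlation), CLN2 by 2.67 ± 0.27. The mitochondrial ribosome list, with 38 of 70 lower, fell by a median of 1.00 (camera adjusted p = 3.97e-12, adjusted p = 0.365 with an estimated correlation, 44 adjusted over the list alone). Core histone genes had 5 of 8 lower, also adjusted over the list alone (median -1.15, camera adjusted p = 0.00263, adjusted p = 0.541 with an estimated correlation), with HTA1, HTA2, HHT1, HTB1 and HHF1 lower and HHF2, HHT2 and HTB2 not past the test, at -0.65, -0.62 and -0.93. HHF1 lost its call without young replicate 2 or without old replicate 1 or 2 (limma adjusted p = 0.0575, 0.0745 and 0.0739), and HTB1 without old replicate 1 or 2 (0.0509 and 0.0502). The galactose list had 5 of 7 lower and GAL80 higher, at 1.01 ± 0.22 (median -1.63, camera adjusted p = 0.0166, adjusted p = 0.541 with an estimated correlation), with 6 lower and 1 higher adjusted over the list alone. It lost its call without young replicate 2 (adjusted p = 0.0520). As deposited the medians of the ribosomal protein, mitochondrial ribosome, core histone and galactose lists were -1.10, -0.43, -0.58 and -1.06, with 0 members called. GAL3 and GCY1 lost their calls in limma without young replicate 2 (adjusted p = 0.0847 and 0.0800), old replicate 1 (0.107 and 0.0652) or old replicate 2 (0.107 and 0.0645), and GAL80 without old replicate 1 or 2 (0.0632 and 0.0633). After quantile scaling the core histone and galactose lists lost their calls (camera adjusted p = 0.131 and 0.162), with HTA1, HTA2, HTB1, HHT1, HHF1, GAL3, GAL7 and GCY1 (limma adjusted p from 0.0505 to 0.257).

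Among the other lists that rose were mating genes, with 14 of 27 higher and 1 lower (median 1.71, camera adjusted p = 0.000173, adjusted p = 0.525 with an estimated correlation, 16 higher and 2 lower adjusted over the list alone), AGA2 by 4.63 ± 0.63. Cell wall genes rose in 16 of 35 cases (median 1.51, camera adjusted p = 1.23e-06, adjusted p = 0.525 with an estimated correlation, 18 adjusted over the list alone), PIR3 by 4.36 ± 0.49. The G2/M and M/G1 list had 14 of 30 higher and 1 lower (median 1.12, camera adjusted p = 5.09e-05, adjusted p = 0.541 with an estimated correlation, 16 higher and 2 lower adjusted over the list alone), BUD4 by 2.24 ± 0.24. DNA damage genes had 8 of 26 higher and 3 lower (median 0.62, camera adjusted p = 0.00277, adjusted p = 0.365 with an estimated correlation, 10 higher and 3 lower adjusted over the list alone), RAD54 by 1.87 ± 0.17.

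Of the lists that fell, ribosome biogenesis had 23 of 80 genes lower, also adjusted over the list alone (median -1.06, camera adjusted p = 2.43e-10, adjusted p = 0.724 with an estimated correlation), RLP7 at -2.37 ± 0.28. Daughter-specific genes fell in 8 of 13 cases (median -1.36, camera adjusted p = 2.25e-05, adjusted p = 0.365 with an estimated correlation, 9 adjusted over the list alone), DSE3 at -2.60 ± 0.19. Glycolysis and fermentation had 4 of 18 lower and 2 higher (median -1.08, camera adjusted p = 0.0162, adjusted p = 0.880 with an estimated correlation, 10 lower and 2 higher adjusted over the list alone), ADH1 at -2.30 ± 0.54. Ergosterol genes had 6 of 23 lower, also adjusted over the list alone (median -0.66, camera adjusted p = 0.00263, adjusted p = 0.686 with an estimated correlation), ERG2 at -1.52 ± 0.29. The Msn2/4 stress list had 7 of 32 lower and 1 higher, also adjusted over the list alone (median -0.68, camera adjusted p = 0.0111, adjusted p = 0.880 with an estimated correlation), the aldehyde dehydrogenase gene ALD3 at -2.06 ± 0.39. Proteasome genes had 5 of 33 lower (median -0.62, camera adjusted p = 4.64e-05, adjusted p = 0.541 with an estimated correlation, 4 adjusted over the list alone), RPT6 at -1.03 ± 0.23. The respiratory chain list had 2 of 35 lower, COX5B and CYC7 at -0.91 and -1.16 (median -0.57, camera adjusted p = 0.0165, adjusted p = 0.880 with an estimated correlation, 0 adjusted over the list alone). As deposited the respiratory, proteasome, ergosterol and Msn2/4 medians were near 0, at -0.004, -0.06, -0.09 and -0.11. Those of ribosome biogenesis, glycolysis and the daughter-specific genes were -0.49, -0.51 and -0.79, and of these 7 lists only the last had a lower call. Without young replicate 2 the glycolysis, respiratory and Msn2/4 lists lost their calls (camera adjusted p = 0.1002, 0.575 and 0.424), and without over-expression replicate 1 the first 2 did (0.119 and 0.0987). After quantile scaling the glycolysis, respiratory, Msn2/4, proteasome and ergosterol lists lost theirs (0.444, 0.600, 0.720, 0.943 and 0.324), with CYC7, COX5B, ALD3, RPT6 and ERG2 (limma adjusted p from 0.0516 to 0.546). In limma ADH1, CYC7 and COX5B lost their calls without young replicate 1 (adjusted p = 0.0550, 0.0509 and 0.0626) and 2 (0.0717, 0.0610 and 0.0895), and CYC7, COX5B and RPT6 without old replicate 1 (0.0553, 0.0866 and 0.0581) or 2 (0.0547, 0.0867 and 0.0577).

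URA3 stood 2.29 ± 0.26 above young in the libraries labelled over-expression (limma adjusted p = 0.00828). The median shift as deposited was 0.53, or 1.44-fold, with -0.23 and 1.27 within replicate numbers 1 and 2, and -0.26 on RPKM before the factor (8.65 ± 0.63 against 8.08 ± 0.41, n = 2, exact permutation p = 0.667). The lowest of the 5 groups by level shifted by 1.35 and the highest by -0.06. Genes near chromosome ends stood at 1.09 against -0.09 elsewhere, 91 rising and 4 falling (camera p = 2.39e-11, p = 0.0868 with an estimated correlation), and chromosome XII at 0.25.

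The last comparison sets the changes against each other, to ask whether the libraries labelled over-expression move back along the change with age. Across genes, which are not independent replicates, the change from young to old and the further change to the libraries labelled over-expression had a covariance of 0.039 (Pearson r = 0.159), where 100 simulations of unchanged groups sharing the old libraries gave -0.086. Simulations with the residual spread of a fit that has the replicate number as a block gave -0.039. With 1 old library in each comparison the observed covariance was 0.211 and 0.027. A difference between replicate numbers enters both terms of this split with the same sign and raises both values, so they do not test a reversal. The observed covariance was not negative, with or without the split. A covariance over genes cannot see a shift common to all genes, so it does not answer the question for that shift. On the deposited scale the median shift was 0.91 from young to old and -0.36 from old to over-expression, opposite in sign. The exact permutation test of the library medians gave p = 0.333 and 0.667. The changes of old and of the libraries labelled over-expression against the shared young libraries had a covariance of 1.16 (r = 0.979), against 0.086 in the simulations, a difference of 1.08. Of the 806 and 977 genes called higher 796 were shared, and of the 545 and 731 called lower 524 were shared, while 0 were called in opposite directions. Independent lists of these lengths would share 129 and 65.3 genes, and simulations of unchanged groups against the shared young libraries gave 0.1 in each direction. The first value leaves out the shared young libraries and the second the effects, so neither tells how many calls those libraries make common. With 1 young library in each comparison, a split chosen after the result was seen, the covariance was 0.963 and 0.946 (r = 0.694 and 0.677). Most of it thus remained without a shared library. The overlap of calls was not split in this way.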

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

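The scalings without the factor, the block with quantile scaling, the estimated correlation with the block, the list tests under quantile scaling and the shifts within a replicate number were chosen after the data were seen, and the cause of the differences below was not tested. Filters at a mean of 5 or none removed no gene and so test nothing. Without these filters, and without counts whose main value was 0, 29 of 56 counts of genes kept within a factor of 1.5, as did 35 of 45 counts of lists, and 30 of 36 median shifts moved by less than the spread between libraries. Of the 3159 values for named genes 2307 stayed the same. For a called gene this means the same direction and call. For an uncalled gene it means a move smaller than its residual spread, whatever its sign. A further 686 lost a call, 41 gained one, 121 uncalled values moved by more, and 4 values of called genes turned sign. Sign turns of uncalled genes are not counted. Of the 585 values for called lists 445 kept direction and call, 130 lost the call and 10 turned sign. The median gene had 1206 to 1849 reads in the 6 libraries. With 2 libraries per group and the spread seen here, simulated log2 changes of 1, 2 and 3 in old against young were called in 14.4%, 79.9% and 92.9% of genes. Only 200 of 6099 genes were changed there. With 1351 called in the data the adjusted threshold is less strict, so these shares are not the power of that comparison. The deposited scale was not simulated. Over-expression against old was simulated only with the replicate block, where 65.0%, 93.8% and 96.9% were called.

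For old against young, genes called relative to the library median numbered 96 with only the compared groups in the fit, 579 after quantile scaling and 460 with ERCC scaling, against 1351, and 0 to 1621 with 1 library left out. As deposited they numbered 79 to 479 with 1 library left out, against 614. For over-expression against old the deposited count was 0 to 2 with 1 library left out. For over-expression against young the count relative to the median was 784 with only the compared groups, 938 after quantile scaling and 288 with ERCC scaling, against 1708, and 0 to 1958 with 1 library left out. The deposited count, 375, became 1208 on RPKM before the factor and 53 to 284 with 1 library left out.

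By the labels, libraries of different groups share only a replicate number. Yet old and over-expression libraries of the same number were closer over genes (Pearson r = 0.980 and 0.987) than the 2 libraries of old (0.949) or of over-expression (0.953). The fits without a replicate term leave this in the residual spread. Deviations of same-numbered libraries from their group means correlated at 0.530 (old and young), 0.669 (old and over-expression) and 0.573 (over-expression and young), over 2 numbers, which does not establish pairing. With the replicate number as a block the counts relative to the median were 2890 (1429 higher, 1461 lower), 1 and 3142 for the 3 comparisons, with quantile scaling as well 2510, 1 and 2750, and as deposited 746, 0 and 492. The 1 gene was URA3 (limma adjusted p = 0.0208 with the block, 0.00151 with quantile scaling too, 0.123 to 1.00 over the other alternatives). In old against young the core histone genes HTB2, HHF1 and HHT2, not called without the block, passed with it (limma adjusted p = 0.0233, 0.0132 and 0.0328). Lists past camera with the block numbered 18, 5 and 18, and 0 in each with an estimated correlation too.

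The median shift of old against young was -0.18 on RPKM before the factor and 0.14 and 1.66 within replicate numbers 1 and 2, and that of over-expression against young -0.26, -0.23 and 1.27. Lists past camera numbered 0 in every comparison with an estimated correlation and 0 in fry for over-expression against old, where leaving out 1 library gave 6 to 12. Some called lists and called named genes turned sign as deposited. In old against young these were the respiratory (0.39), mitochondrial ribosome (0.0747), Msn2/4 (0.47), proteasome (0.41) and ergosterol (0.23) lists. GAL3 (0.15), RPT6 (0.0037), PUP2 (0.0478) and RPN11 (0.14) turned there as well. In over-expression against old the mating (-0.21) and cell wall (-0.23) lists turned. Quantile scaling ended 14 list calls and 51 calls of named genes. It also ended the proteasome call in old against young, where the median turned to 0.0153. The Msn2/4 median in over-expression against old ran from -0.44 without old replicate 1 to 0.0700 without old replicate 2, and was 0.0075 without over-expression replicate 1.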

Other observations

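The tests of explanations in this part were all chosen after the results were seen, as were the gene groups of the first paragraph. Retrotransposon genes rose in old cells. Of 54 Ty reading frames 33 rose and 0 fell relative to the library median (median 2.65, limma adjusted p 0.05; camera adjusted p = 7.56e-18 over the 5 groups of this kind, adjusted p = 0.136 with an estimated correlation), with the Ty1 frame YER160C at 184 and 189 in young and 10878 and 19923 in old. The Y' helicase genes at chromosome ends rose in 5 of 6 cases (median 2.78, camera adjusted p = 0.000102, adjusted p = 0.0652 with an estimated correlation), YRF1-6 by 3.99. These copies share reads, so which copy changed is uncertain. The vitamin B6 genes SNZ1 and SNO1 rose by 2.65 and 2.82 (limma adjusted p = 0.00444 and 0.00908). The group formed by their names is not used here, since it held SNO4, which is no vitamin gene. Seripauperin genes rose in 2 of 9 cases (median 1.50, camera adjusted p = 0.00331, adjusted p = 0.151 with an estimated correlation). The ASP3 copies beside the rDNA, whose 4 values are equal, had a median of 0.89 with 0 called (camera adjusted p = 0.0348, adjusted p = 0.363 with an estimated correlation).

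TAR1 took 0.0512% and 0.0666% of reads in young replicates 1 and 2, 2.82% and 1.18% in old, and 3.47% and 0.928% in the libraries labelled over-expression. The 21 genes of the mitochondrial genome had a median of 0.92 in old against young, 1.24 and 0.51 within replicate numbers 1 and 2.

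The median shift with age was 0.14 in replicate number 1 and 1.66 in number 2. Counting error of the ERCC transcripts is argued against, since the largest standard error of their mean level in any library was 0.0671. A spike-in amount per cell that differed between libraries stays open. Number 2 minus number 1 of the library medians was -0.58 in young, 0.93 in old and 0.89 in the libraries labelled over-expression, so that old and young differ in it by 1.51, and no value here parts the spike-in dose from RNA per cell. A real rise of RNA per cell with age also stays open, untested.

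Low genes rose more with age than high genes. Sorting on the same libraries is argued against as the whole cause, since with 5 groups formed in replicate number 1 and changes taken from number 2 the lowest still stood 1.04 above the highest. Gene length is argued against likewise, since within each of 5 groups by length the difference was at least 0.70 (93.9% of genes have a length). A uniform background of reads in old libraries, such as residual DNA or spurious transcription, may add to genes near the floor. The 303 genes lowest in the young library of the other number went from a median of 1.52 to 4.21 RPKM before the factor, and the smaller interquartile range of log2 RPKM in old was 1.51, but genes this low decide nothing.

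H3 and H4 transcripts were not called higher in the libraries labelled over-expression. Reads split between the near-identical copies are argued against, since the summed copies of H3 or H4 were at most 0.33 higher within a replicate number on the log2 scale relative to the library median. An exchange of an old with an over-expression library of the same number is argued against by URA3, whose gap as labelled is wider by 1.56 than the widest gap of any gene after such an exchange. An exchange between different numbers would put a low and a high URA3 library in each group. The deposited URA3 values would pair as 827 with 5390 and 1272 with 8738, and so overlap (gap -2.85 relative to the library medians). URA3 thus argues against this exchange too. The other genes do not decide it, since it would part the libraries by replicate number. There gaps reach 3.41 (YOL103W-A, a transposon gene) and 4116 genes do not overlap. Plasmid genes outside the annotation, a short induction and an exchange of both libraries were not tested.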
